A study of Mus musculus with 8 samples.

How the data were processed

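The deposited table gives 1 RPKM value per gene and library for 47729 Ensembl gene identifiers and 8 libraries, with replicates in separate columns. Per the labels, RNA was extracted from sorted cells with a column kit for small samples, copied into full-length cDNA by Smart-seq2 and made into libraries by Nextera XT tagmentation. Per the submitters' processing notes, the genome build was GRCm38 and edgeR was used. The aligner, the read counter, the annotation release, the filters, the strandedness and whether a scaling factor entered the RPKM are not given in the sources used here. Whether low values had been removed by the authors is likewise not given, and 21036 genes were at 0 in all libraries.

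Symbols and coordinates came from GENCODE M21, also on GRCm38, which named 47224 of the identifiers and left 505 without a match. Between 80.8% and 82.7% of the small values in each library were whole multiples, within 0.01, of a value that stands for 1 read, which gave the effective number of reads per library. The reads came out whole in every library for 21445 genes. The statement that a gene is listed at 0 refers to the deposited value, and at these depths 3 reads, the most that a count of 0 allows, would be between 0.0527 and 0.108 RPKM in a gene of 2 kb. Such limits cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

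Values were taken as log2(RPKM + 1) with no further scaling between libraries. Genes with at least 1 RPKM in at least 2 libraries were tested, 12900 in all. The linear model of limma had 1 coefficient for each of the 5 groups and no covariate, with moderated variances that follow the mean (eBayes with trend). It left 3 residual degrees of freedom, to which the prior added 3.65. P-values were two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The comparisons were 12 h with fresh cells, organoids with fresh cells, organoids with 12 h, and each lone library with fresh cells. With 2 libraries at most per group, outlying libraries were not tested for and random splits of the libraries were not counted.

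The named genes followed a rule written, like the groups, the 22 lists and the main comparisons, before the data were examined. Runs, tests and genes chosen later are given as such. It takes the 8 largest increases and 8 largest decreases among genes that passed, had a mean of at least 5 RPKM over the 4 libraries compared and did not overlap between groups, leaving out predicted, ribosomal protein, small RNA and mitochondrial genes. It adds up to 4 passing members of each list, by size of change, and 13 genes whatever their result, namely Tet1, Tet2, Tet3, Dnmt1, Dnmt3a, Dnmt3b, Lgr5, Epcam, Krt19, Sox9, Spp1, Alb and Mki67.

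The 22 lists, of 463 entries from textbook knowledge, were ductal identity, ductal transport and cilium, hepatocyte markers, Wnt targets and organoid stem markers, S phase, G2 and M phase, DNA methylation machinery, Polycomb and chromatin modifiers, YAP and TEAD targets, ERK targets and ErbB ligands, immediate early and dissociation stress, NF-kB and inflammatory mediators, interferon response, cholesterol synthesis, MYC and ribosome biogenesis, glycolysis, NRF2 targets, p53 targets, and markers of mesenchymal and stellate, mesothelial, endothelial and immune cells. Uhrf1 and Bmi1 each stand in a pair of lists. Only 3 of 14 mesenchymal and stellate, 3 of 8 mesothelial, 2 of 14 endothelial and 3 of 17 immune markers passed the expression filter. Each list was tested with camera in limma at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison, and again with the correlation estimated from the data. With the estimated correlation 0 of the 26 list calls in the 3 replicated comparisons held, and 0 of the 4 at 24 h and 9 in the library titled 48h. The estimate was under 0.01 for ductal identity (−0.0106), transport and cilium (−0.0021), interferon response (0.005) and mesothelial markers (−0.33), whose calls ended too. Correlation between genes does not account for those losses, so a lost call does not by itself show such correlation. With the correlation estimated, camera takes its p-value from the 3 residual degrees of freedom of the model. The preset run draws on the far larger number of genes, so a call can be lost through the degrees of freedom alone. List members were also counted at an adjusted p under 0.05 over all genes and adjusted over the list alone. Where camera gave no call, its direction could differ in sign from the median, as for Wnt, YAP and MYC genes at 12 h and DNA methylation genes in organoids. Setting genes at 0 in a whole group to a floor of 3 reads moved the 66 list medians by at most 0.13. Results for 3 genes are not reported here by name, though these genes stay in the counts and list tests.

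The procedure was run on simulated tables with the gene spreads of these data, 10 simulations of 200 changed genes each. Each gene was drawn independently of the others. With equal spread in all libraries, 16-fold changes were recovered in 95.4% of cases for 12 h with fresh cells, 94% for organoids with fresh cells and 95.1% for organoids with 12 h, and 4-fold changes in 33.1%, 29% and 34.1%. The mean number of false calls was 9.5, 7.7 and 10.1. With the spread of each library as estimated, recovery fell to 80.4%, 81.1% and 82.4% at 16-fold and to 7.5%, 9.5% and 14.4% at 4-fold, with 1.2, 3.6 and 16.9 false calls. A list shifted by −2 on the log2 scale was called in 10 of 10 simulations in each setting. As the simulated genes were independent, this does not test the preset correlation. In these data the estimated correlation reached 0.82, for glycolysis.

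The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.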

Results

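RNA was measured in mouse liver ductal cells before and after they were placed in organoid culture, to see how their transcriptome changed. The cells came from healthy livers of adult male C57/B6 mice and were sorted for EpCAM, a surface adhesion protein carried by bile duct epithelium. The 8 low-input libraries comprised 2 of freshly sorted cells, 2 of cells cultured for 12 h in Matrigel and organoid medium, 1 of cells cultured for 24 h, 1 titled 48h, and 2 of organoids after 6 days. The library titled 48h carries a 24 h time point in its other labels and was kept apart under its title. Expression was given by the authors as RPKM, reads scaled to gene length and library depth, and the values corresponded to between 13833143 and 28468920 effective reads per library. At 1 read, a gene of 2 kb would show between 0.0176 and 0.0361 RPKM. The number of genes at 1 RPKM or more was lowest in the 24 h library, at 8814, and between 10605 and 11263 in the other 7. Genes above 0 numbered 19279 and 21132 in the fresh libraries, 15632 and 16157 at 12 h, 13895 at 24 h, 16911 in the library titled 48h and 18496 and 19061 in the organoids, an order that the effective reads do not follow. Of 1302 genes with a mean of at least 50 RPKM over the libraries, 2 and 0 were below 1 RPKM in the fresh libraries, 5 and 5 at 12 h, 16 at 24 h, 5 in the library titled 48h and 12 and 7 in the organoids. Falls of low genes and values of 0 at 12 h and 24 h were therefore not separated from a lower capture of molecules in those libraries. The share of summed RPKM from mitochondrial genes was 7.21% and 5.52% in the fresh libraries, 8.83% and 8.68% at 12 h, 9.87% at 24 h, 5.94% in the library titled 48h and 3.92% and 4.93% in the organoids. Nothing in the labels says that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. Intervals of counting error were not attached to RPKM values, and a fold on the log2(RPKM + 1) scale understates changes of low genes.

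At 12 h of culture, 10 of 25 immediate early, 7 of 24 inflammatory and 14 of 24 hepatocyte genes tested had fallen below their level in fresh cells, and targets of p53 moved in both directions. The calls of the first 3 lists by camera did not hold once the correlation between genes was estimated from the data. That run tests on 3 degrees of freedom, so the loss does not show that correlation undoes the calls. Fos, an immediate early transcription factor, fell from 362 ± 11.9 to 51.5 ± 13.4 RPKM (SD, n = 2 each). Cxcl2, a chemokine that attracts neutrophils, fell 20.8-fold, from 1448 ± 106 to 69.6 ± 0.288 RPKM. Alb, the plasma albumin of hepatocytes, fell 24.2-fold, from 574 ± 122 to 23.8 ± 1.07 RPKM. Phlda3, a p53 target that restrains AKT, rose 16.8-fold, from 7.01 ± 0.487 to 118 ± 12.4 RPKM. In the comparison by limma with Benjamini-Hochberg adjustment, the fitted log2 changes were −2.81 (SE 0.36, adjusted p = 0.0239) for Fos, −4.36 (SE 0.63, adjusted p = 0.026) for Cxcl2, −4.52 (SE 0.69, adjusted p = 0.027) for Alb and 3.88 (SE 0.43, adjusted p = 0.0189) for Phlda3. On GRCm38, Fos lies at chromosome 12:85473890-85477273, Cxcl2 at 5:90903871-90905938, Alb at 5:90460897-90476602 and Phlda3 at 1:135766119-135769136, all annotated as protein-coding genes.

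Of 12900 genes tested at 12 h, 878 passed an adjusted p of 0.05, 398 higher and 480 lower. Each of the 878 differed by at least 2-fold on the fitted scale, with both libraries of 1 group above both of the other. Of all 12900 genes 62.2% had no overlap, where chance alone leaves 33.3%. With 2 libraries per group a gene can hardly pass otherwise, so the lack of overlap adds little support. The median log2 change of genes with a mean of at least 5 RPKM was 0.40, and after each library was centred on its median the split became 270 higher and 910 lower. With only genes at a mean of at least 5 RPKM tested it became 403 higher and 197 lower, and with library weights 870 higher and 731 lower. Which direction held the majority thus depended on the filter and on the weighting of libraries. Among the largest increases were Tnfrsf22, which encodes a decoy receptor for TRAIL (0.738 ± 0.0776 to 42.4 ± 11.1 RPKM), and Slc4a11, a membrane transporter (3.21 ± 0.459 to 64.1 ± 2.17 RPKM). Dctd, which makes dUMP for thymidylate synthesis (0.905 ± 0.41 to 24.4 ± 5.84 RPKM), and Fxyd5, a regulator of the sodium pump (2.11 ± 0.132 to 33.1 ± 11.1 RPKM), also rose. Tnfrsf23, the neighbour and paralog of Tnfrsf22, rose 14.0-fold, and how reads were shared between the pair is not given in the sources used here. The largest decreases included Krt23, a keratin (490.2 ± 71.3 to 13.5 ± 14 RPKM), and Ivl, the envelope protein involucrin (57.1 ± 4.43 to 0.857 ± 1.21 RPKM).

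Of 24 hepatocyte marker genes tested at 12 h, 14 passed, all lower, or 17 lower adjusted over the list alone, with a median log2 change of −2.88 (limma camera, adjusted p = 3e-13; adjusted p = 0.236 with an estimated correlation). The fitted change was above 0 for 3 of the 24. Ahsg, the secreted plasma protein fetuin-A, fell from 57.3 ± 19.9 to 0.159 ± 0.00414 RPKM, and Apoa1, the main protein of high-density lipoprotein, fell from 71.1 ± 44.9 to 1.03 ± 1.34 RPKM. The lipid carrier gene Fabp1, at 41.8 ± 30 RPKM in fresh cells, was listed at 0 in both 12 h libraries.

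The immediate early and dissociation stress list fell in 10 of 25 members, or 16 adjusted over the list alone (camera adjusted p = 3.65e-12; adjusted p = 0.284 with an estimated correlation). Zfp36, which destabilises cytokine messages, fell 10.8-fold to 28.3 ± 4.53 RPKM, and Atf3, a stress-induced transcription factor, fell 11.9-fold to 41.7 ± 17.3 RPKM. The NF-kB and inflammatory list fell in 7 of 24 members, or 12 adjusted over the list alone (camera adjusted p = 3.75e-10; adjusted p = 0.457 with an estimated correlation). Icam1, an adhesion molecule for leukocytes, fell 9.95-fold, from 1087 ± 262 to 109 ± 13.6 RPKM, and Cxcl5, another neutrophil chemokine, fell 6.63-fold, from 1287 ± 164 to 194 ± 136 RPKM. The only baseline was cells just dissociated and sorted, so these falls cannot be told apart from the end of a response to isolation.

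Genes of ductal transport and the cilium fell in 4 of 18 members at 12 h, or 8 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0127; adjusted p = 0.29 with an estimated correlation). Pkhd1, which encodes the ciliary protein fibrocystin, fell 23.0-fold to 0.519 ± 0.348 RPKM, and Slc5a1, a sodium-glucose cotransporter, fell 14.4-fold to 2.28 ± 2.44 RPKM. The ductal identity list was lower by camera (adjusted p = 0.0198; adjusted p = 0.29 with an estimated correlation), although the 1 of its 23 members to pass, also when adjusted over the list alone, was higher. That gene was Onecut2, a transcription factor of liver and bile duct development, which rose 4.19-fold to 61.6 ± 0.655 RPKM. The cholesterol synthesis list was lower by camera (adjusted p = 0.00128; adjusted p = 0.896 with an estimated correlation), with 0 of 22 genes passing by limma and 5 lower adjusted over the list alone. Mesothelial markers were lower by camera (adjusted p = 0.0363; adjusted p = 0.357 with an estimated correlation), with 2 of 3 lower over all genes and over the list alone, Gpm6a at 0.0069 ± 0.00975 RPKM and Nkain4 listed at 0. Centring on the library medians ended the calls of transport and cilium, ductal identity (each adjusted p = 0.0567) and mesothelial markers (0.0798). Centring shifts all genes of a library alike, and their medians moved by a common amount, from −1.06 to −1.48, from −0.85 to −1.27 and from −2.96 to −3.38. Neither this shift nor the loss of the calls shows that scaling accounts for the fall. The median of ductal identity, −0.85, was −0.55 without 12 h replicate 2. The call of transport and cilium also ended at a mean of at least 5 RPKM (0.224) and with only the groups compared (0.101). Ductal identity lost its call after quantile normalization (0.148), where its median was −0.66 against −0.85. Mesothelial markers lost theirs with only the groups compared (0.146).

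The p53 targets moved both ways at 12 h, with 2 of 16 higher and 3 lower, the same numbers adjusted over the list alone (camera adjusted p = 0.531; adjusted p = 0.948 with an estimated correlation). Bax, a promoter of apoptosis, rose 5.21-fold to 243 ± 15.5 RPKM, whereas Sesn2 fell 9.27-fold and the death receptor gene Fas, at 22.3 ± 0.826 RPKM in fresh cells, was listed at 0. Of 15 NRF2 targets, 4 rose and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.531; adjusted p = 0.948 with an estimated correlation). Nqo1, a quinone reductase, rose 13.4-fold to 32.8 ± 12.8 RPKM. Among YAP and TEAD targets, 2 of 23 rose and 3 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.742; adjusted p = 0.965 with an estimated correlation), with Igfbp3 15.6-fold higher and Ankrd1 6.05-fold lower. Of 3 immune markers 1 was lower, also over the list alone (camera adjusted p = 0.221; adjusted p = 0.539 with an estimated correlation), namely Csf1r, a receptor of macrophages, which fell 29.8-fold to 0.27 ± 0.244 RPKM (adjusted p = 0.0308). Of 2 endothelial markers tested, too few for camera, 1 was lower, also over the list alone, namely Eng, listed at 0 against 1.92 ± 0.0347 RPKM (adjusted p = 0.0395). The other 10 lists tested by camera at 12 h had adjusted p between 0.256 and 0.939. Epcam stood at 1019 ± 221 against 1101 ± 60.9 RPKM in fresh cells (adjusted p = 0.858), and Sox9, a ductal transcription factor, at 245 ± 81.2 against 270.4 ± 43.9 RPKM (adjusted p = 0.804). Krt19, a ductal keratin, was at 692 ± 616 against 1356 ± 416 RPKM (adjusted p = 0.296), with 1128 and 257 in the 12 h libraries. Spp1, the secreted protein osteopontin, was at 9178 ± 3578 against 15961 ± 2510 RPKM (adjusted p = 0.421). Dnmt1, Dnmt3a, Dnmt3b, Tet2, Tet3, Lgr5 and Mki67 did not pass at 12 h either, with adjusted p between 0.103 and 0.989.

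By limma, 0 genes passed without either fresh library (1878 and 1672 at an unadjusted p under 0.05) or without 12 h replicate 1 (3458), 94 passed without 12 h replicate 2, and the lone library left in its group was assumed to vary like the other groups. Leaving out 1 library also ended the camera call of ductal identity (fresh replicates 1 and 2, 12 h replicates 1 and 2; adjusted p from 0.0508 to 0.0955), of transport and cilium (12 h replicate 1 and either organoid library; 0.0795 to 0.108), of mesothelial markers (either 12 h or either organoid library; 0.058 to 0.132) and of cholesterol synthesis (12 h replicate 2; 0.13).

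**Figure D1:**
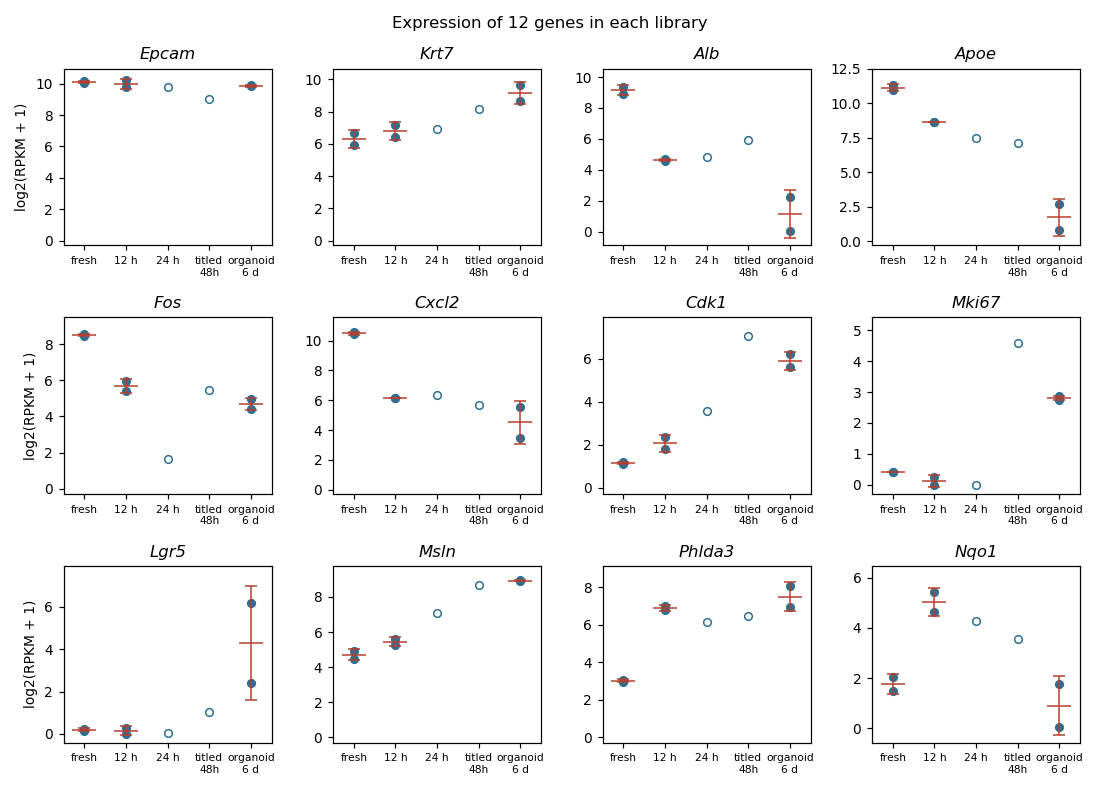
Expression of 12 genes on the log2(RPKM + 1) scale in each library, by group; filled points are replicate libraries with their mean and SD as bars, and open points are groups with 1 library. Alb and Cxcl2 were highest in the fresh libraries, Cdk1 was highest in the library titled 48h and the organoids, and Lgr5 differed widely between the organoid libraries.

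After 6 days, 32 of 33 G2 and M phase genes tested were higher in the organoids than in fresh cells and 15 of 24 hepatocyte markers lower. Neither list was called by camera with an estimated correlation, on 3 degrees of freedom. Cdk1, the kinase that drives entry into mitosis, rose 49.8-fold, from 1.22 ± 0.0805 to 60.7 ± 17.7 RPKM (SD, n = 2 each). Ccnb2, a mitotic cyclin, rose 48-fold, from 2.56 ± 2.54 to 123 ± 19.7 RPKM. Msln, which encodes the surface protein mesothelin, rose 19.0-fold, from 25.3 ± 5.62 to 482 ± 9.39 RPKM. Apoe, a lipid transport protein, fell 713-fold, from 2238 ± 393 to 3.14 ± 3.38 RPKM, and Alb fell 306-fold, to 1.87 ± 2.61 RPKM. In limma with Benjamini-Hochberg adjustment, the log2 changes were 4.77 (SE 0.42, adjusted p = 0.00619) for Cdk1, 5.32 (SE 0.80, adjusted p = 0.0159) for Ccnb2, 4.21 (SE 0.33, adjusted p = 0.00573) for Msln, −9.36 (SE 0.61, adjusted p = 0.00482) for Apoe and −8.01 (SE 0.69, adjusted p = 0.00616) for Alb. On GRCm38, Cdk1 lies at chromosome 10:69335146-69352938, Ccnb2 at 9:70407692-70421547, Msln at 17:25748613-25754378 and Apoe at 7:19696109-19699188, all protein-coding.

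Between organoids and fresh cells 1301 of 12900 genes passed, 664 higher and 637 lower, each by at least 2-fold and without overlap between the libraries. Of all genes tested 64.7% had no overlap. The median log2 change of genes with a mean of at least 5 RPKM was 0.27, and centring on the median gave 498 higher and 939 lower, whereas testing only genes with that mean gave 707 higher and 433 lower. The largest increases included Cdh17, a cadherin of intestinal epithelium (0.112 ± 0.0696 to 79.5 ± 70.5 RPKM), and Gmnn, which encodes the replication licensing inhibitor geminin (0.798 ± 0.432 to 62.8 ± 24.3 RPKM). Ppic, a cyclophilin (4.82 ± 1.68 to 222 ± 34.6 RPKM), and Igfbp4, which binds insulin-like growth factors (5.50 ± 0.372 to 224 ± 99.6 RPKM), rose as well. Among the largest decreases, Fosl1, an AP-1 transcription factor, fell 114-fold to 8.44 ± 8.88 RPKM. Ces1d and H2-Q6 fell 1136-fold and 342-fold, and both belong to families of similar genes in which read assignment is uncertain.

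G2 and M phase genes rose in 32 of 33 members, or 33 adjusted over the list alone, with a median log2 change of 3.20 (camera adjusted p = 2.32e-19; adjusted p = 0.302 with an estimated correlation). Plk1, a mitotic kinase, rose from 0.142 ± 0.116 to 37.2 ± 30.8 RPKM, and Mki67, the proliferation marker Ki-67, rose 18.8-fold to 6.01 ± 0.355 RPKM (limma adjusted p = 0.0181). S phase genes rose in 7 of 30 members, or 19 adjusted over the list alone (camera adjusted p = 4e-07; adjusted p = 0.538 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, rose 35.0-fold to 46.4 ± 12 RPKM, and Tyms, thymidylate synthase, rose 7.49-fold to 17.4 ± 3.03 RPKM.

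Glycolysis genes were higher by camera, with 3 of 16 higher, or 8 adjusted over the list alone (adjusted p = 0.00142; adjusted p = 0.581 with an estimated correlation). Pkm, a pyruvate kinase, rose 27.4-fold to 956 ± 788 RPKM, with 1513 RPKM in organoid replicate 1 and 398 in replicate 2. All 16 glycolysis genes were higher in replicate 1, with a median log2 ratio of 2.34 between the organoid libraries. Without organoid replicate 1 the glycolysis call ended, at an adjusted p of 0.0639.

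**Figure D2:**
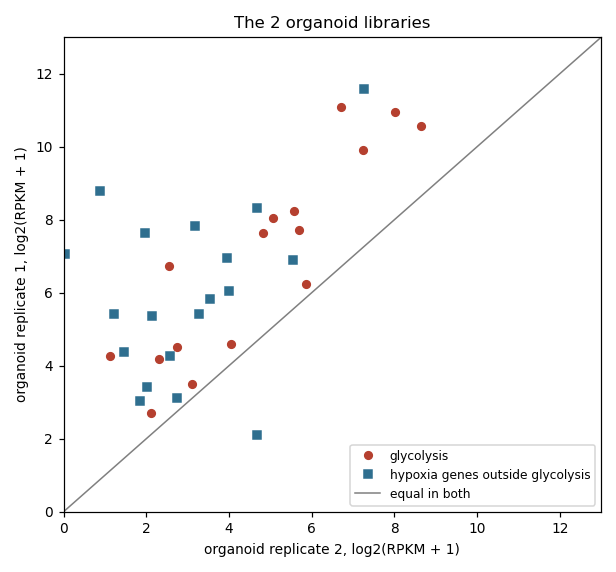
Expression of 16 glycolysis genes and 19 hypoxia-response genes outside that list in organoid replicate 2 (horizontal) and replicate 1 (vertical), each on the log2(RPKM + 1) scale, 1 point per gene, with a line of equal expression. All 16 glycolysis genes and 18 of the 19 others lie above the line, and the exception is Car9.

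Hepatocyte markers fell in 15 of 24 members, or 18 lower and 1 higher adjusted over the list alone (camera adjusted p = 2.01e-12; adjusted p = 0.136 with an estimated correlation). The immediate early list fell in 15 of 25 members, or 19 adjusted over the list alone (camera adjusted p = 2e-15; adjusted p = 0.136 with an estimated correlation). Egr1, an immediate early transcription factor, fell 32.6-fold to 13.1 ± 10.2 RPKM, and Atf3 fell 42.4-fold. NF-kB and inflammatory genes fell in 7 of 24, or 14 adjusted over the list alone (camera adjusted p = 3.34e-07; adjusted p = 0.538 with an estimated correlation), including Cxcl10, an interferon-induced chemokine, which fell 77.2-fold. The fitted change was above 0 for 3 of the 24. The organoid libraries differed, with a median log2 difference from fresh cells of −2.88 for this list in replicate 1 and −1.46 in replicate 2. Interferon response genes fell in 7 of 19, or 9 adjusted over the list alone (camera adjusted p = 1.26e-06; adjusted p = 0.136 with an estimated correlation). Among them, Ifit3 fell 28.9-fold to 0.497 ± 0.0586 RPKM and Isg15, a ubiquitin-like protein, fell 11.0-fold to 1.5 ± 0.452 RPKM.

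Ductal transport and cilium genes fell in 6 of 18 members, or 7 adjusted over the list alone (camera adjusted p = 0.00104; adjusted p = 0.164 with an estimated correlation). The call ended when only genes at a mean of at least 5 RPKM were tested (adjusted p = 0.178). In the other settings at the preset correlation it was between 0.000104 and 0.00971. Cftr, the chloride channel of bile duct cells, fell 21-fold to 0.37 ± 0.26 RPKM, and Sctr, the secretin receptor gene, was listed at 0 in both organoid libraries against 3.31 ± 1.41 RPKM. Ductal identity genes went both ways, with 2 of 23 higher and 1 lower, or 4 and 4 adjusted over the list alone (camera adjusted p = 0.287; adjusted p = 0.538 with an estimated correlation). Krt7, a ductal keratin, rose 7.51-fold to 610 ± 283 RPKM, and Cldn4, a tight junction protein, fell 7.57-fold to 344 ± 226 RPKM. Epcam (927 ± 37.9 RPKM, adjusted p = 0.692), Krt19 (1623 ± 420.2 RPKM, adjusted p = 0.832), Spp1 (7965 ± 3003 RPKM, adjusted p = 0.298) and Sox9 (130 ± 14.1 RPKM, adjusted p = 0.117) did not pass by limma.

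Mesenchymal and stellate markers were lower by camera (adjusted p = 0.00232; adjusted p = 0.215 with an estimated correlation). Of the 3 members tested, out of 14, 1 was lower, or 3 adjusted over the list alone. That gene was Rgs5, a regulator of G protein signals known as a pericyte marker, at 1.07 ± 1.15 against 64.0 ± 4.21 RPKM. Its level at 12 h, given below, was higher than in fresh cells. MYC and ribosome biogenesis genes were lower by camera (adjusted p = 0.000344; adjusted p = 0.581 with an estimated correlation), although the 1 of 23 that passed, the nucleolar chaperone gene Npm1, rose 3.85-fold, and over the list alone 1 was higher and 2 lower. The median log2 difference of that list from fresh cells was −1.88 in organoid replicate 1 and −0.22 in replicate 2. Wnt targets were higher in 2 of 15 and lower in 1, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.245; adjusted p = 0.612 with an estimated correlation), with Sp5, a Wnt-induced transcription factor, 37.6-fold higher. Lgr5, a receptor for R-spondin and a stem cell marker, was at 72.0 RPKM in organoid replicate 1 and 4.21 in replicate 2 against 0.139 ± 0.0563 in fresh cells, and did not pass (log2 change 4.10, SE 1.11, adjusted p = 0.0645). The p53 targets numbered 4 higher and 3 lower of 16, also over the list alone (camera adjusted p = 0.315; adjusted p = 0.85 with an estimated correlation), with Ccng1, a p53-induced cyclin, 12.1-fold higher.

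YAP and TEAD targets numbered 5 higher and 4 lower of 23, also over the list alone (camera adjusted p = 0.936; adjusted p = 0.97 with an estimated correlation), and F3, the tissue factor that starts coagulation, fell 41.1-fold. ERK targets and ErbB ligands numbered 2 higher and 3 lower of 21, also over the list alone (camera adjusted p = 0.245; adjusted p = 0.807 with an estimated correlation), with Hbegf, a ligand of the EGF receptor, 15.7-fold lower. NRF2 targets fell in 3 of 15, or 5 adjusted over the list alone (camera adjusted p = 0.166; adjusted p = 0.581 with an estimated correlation), among them Hmox1, a heme oxygenase, by 8.24-fold. Polycomb and chromatin genes numbered 1 higher, Ezh2, the Polycomb methyltransferase, by 5.30-fold, and 1 lower, Kdm6b, a histone demethylase, by 11.7-fold, of 24, or 0 and 1 adjusted over the list alone (camera adjusted p = 0.936; adjusted p = 0.97 with an estimated correlation). Of 17 DNA methylation genes 0 passed by limma, also over the list alone (camera adjusted p = 0.936; adjusted p = 0.97 with an estimated correlation), and Tet1 lay below the expression filter. Dnmt1, the maintenance methyltransferase, was at 13.5 ± 9.26 against 3.60 ± 1.07 RPKM (adjusted p = 0.133). The adjusted p of Dnmt3a, Dnmt3b, Tet2 and Tet3 lay between 0.282 and 0.72. Of 22 cholesterol synthesis genes 0 passed, also over the list alone (camera adjusted p = 0.494; adjusted p = 0.96 with an estimated correlation). Mesothelial markers numbered 1 higher, Msln, and 2 lower of 3, also over the list alone (camera adjusted p = 0.245; adjusted p = 0.538 with an estimated correlation). Of 3 immune markers 0 passed, and 1 was lower over the list alone (camera adjusted p = 0.368; adjusted p = 0.581 with an estimated correlation). Of 2 endothelial markers tested 0 passed, 1 lower over the list alone, too few for camera.

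By limma, 0 genes passed between organoids and fresh cells without either fresh library (2163 and 1847 at an unadjusted p under 0.05), and 117 passed without organoid replicate 1. The lone library left in its group was assumed to vary like the other groups.

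**Figure D3:**
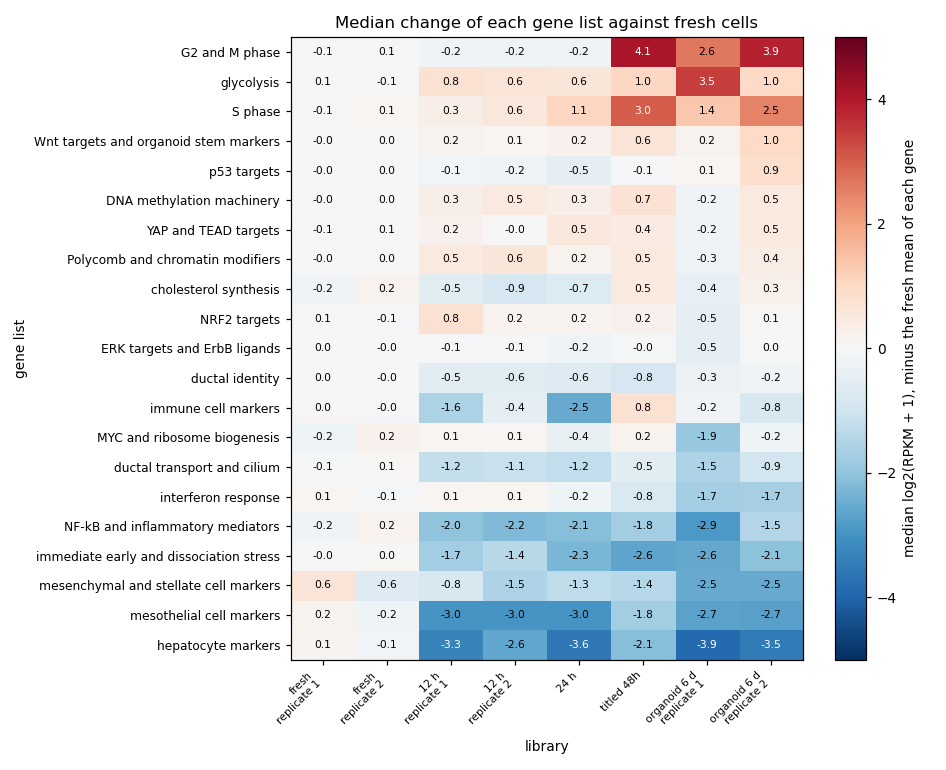
Median change of 21 gene lists in each of the 8 libraries, as log2(RPKM + 1) minus the mean of the fresh libraries for each gene; lists are ordered by their mean in the organoids. G2 and M phase genes were highest in the library titled 48h, at 4.1, and in the organoids, at 2.6 and 3.9, and glycolysis genes were higher in organoid replicate 1, at 3.5, than in replicate 2, at 1.0.

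Between 12 h and 6 days, 23 of 33 G2 and M phase genes rose, and Rgs5 and Nrn1 were among the genes that fell. The G2 and M phase list was not called by camera with an estimated correlation, on 3 degrees of freedom. Cdc20, an activator of the anaphase-promoting complex, went from 0.0616 ± 0.0871 to 62.8 ± 48 RPKM (SD, n = 2 each). Mmp7, a matrix metalloproteinase of epithelia, rose 33.8-fold, from 19.9 ± 5.54 to 671 ± 55.4 RPKM. Rgs5 fell 266-fold, from 284 ± 149 to 1.07 ± 1.15 RPKM, and Nrn1, a membrane protein of neurite growth, fell 107-fold, from 65.1 ± 17.2 to 0.609 ± 0.803 RPKM. The log2 changes in limma with Benjamini-Hochberg adjustment were 5.67 (SE 0.63, adjusted p = 0.0211) for Cdc20, 5.03 (SE 0.58, adjusted p = 0.0224) for Mmp7, −7.12 (SE 0.54, adjusted p = 0.0177) for Rgs5 and −5.43 (SE 0.52, adjusted p = 0.0183) for Nrn1. On GRCm38, Cdc20 lies at chromosome 4:118432901-118437352, Mmp7 at 9:7692090-7699585, Rgs5 at 1:169655501-169695813 and Nrn1 at 13:36725361-36735131, all protein-coding.

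Between these groups 258 of 12900 genes passed, 178 higher and 80 lower in organoids, each by at least 2-fold and without overlap. Of all genes tested 44.9% had no overlap. The median log2 change of genes with a mean of at least 5 RPKM was −0.17. G2 and M phase genes rose in 23 of 33, or 32 adjusted over the list alone (camera adjusted p = 3.85e-31; adjusted p = 0.493 with an estimated correlation), and S phase genes in 1 of 30, Rrm2, or 8 adjusted over the list alone (camera adjusted p = 2.78e-06; adjusted p = 0.517 with an estimated correlation). Aurka, a mitotic kinase, went from 0.00943 ± 0.0133 to 32.4 ± 17.1 RPKM. Glycolysis genes (camera adjusted p = 3.47e-05) and cholesterol synthesis genes (0.00125) were higher with 0 of 16 and 0 of 22 members passing, or 2 and 0 adjusted over the list alone, each at adjusted p = 0.517 with an estimated correlation. The p53 targets were also higher (camera adjusted p = 0.00108; adjusted p = 0.517 with an estimated correlation), with 0 of 16 passing, or 2 adjusted over the list alone.

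Interferon response genes were lower in organoids than at 12 h (camera adjusted p = 1.33e-05; adjusted p = 0.331 with an estimated correlation), with 1 of 19 passing, or 10 adjusted over the list alone. NRF2 targets were lower as well (camera adjusted p = 0.00041; adjusted p = 0.493 with an estimated correlation), with 1 of 15 lower, or 6 adjusted over the list alone. That gene was Nqo1, which fell 27.3-fold to 1.20 ± 1.63 RPKM. Immediate early genes were lower (camera adjusted p = 0.000954; adjusted p = 0.493 with an estimated correlation), with 1 of 25 passing, Klf6, or 8 adjusted over the list alone. MYC and ribosome biogenesis genes were lower (camera adjusted p = 0.000182; adjusted p = 0.517 with an estimated correlation) with 0 of 23 passing, also over the list alone. The other 12 lists tested by camera had adjusted p between 0.0798 and 0.93, hepatocyte markers among them at 0.143. Cd74, the invariant chain of class II antigen presentation, fell 44.4-fold to 2.67 ± 1.09 RPKM, whereas Cxcl5 rose 9.78-fold to 1900 ± 444 RPKM and Msln 11.1-fold. Of the 13 genes given whatever their result, Mki67 passed between organoids and 12 h (adjusted p = 0.0335), Tet1 was not tested, and the other 11 had adjusted p between 0.0603 and 0.891.

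By limma, 0 genes passed between organoids and 12 h without either fresh library (1679 and 1687 at an unadjusted p under 0.05), without either 12 h library (2777 and 2767) or without organoid replicate 1 (2074), and 0 passed with only these groups in the model (1686). Leaving out 1 library ended the camera call of glycolysis (organoid replicate 1, adjusted p = 0.123), p53 targets (organoid replicate 2, 0.106) and cholesterol synthesis (12 h replicate 2, 0.148, and organoid replicate 2, 0.0552).

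The 24 h library and the library titled 48h had no replicate, so single genes are given here by their levels alone. Counts by limma for them rest on an assumed spread. Cdk1 was at 11.0 RPKM at 24 h and 131 in the library titled 48h, Rrm2 at 21.8 and 106, and Mki67 at 0 and 23.1. Fos stood at 2.15 and 43.4 RPKM, Alb at 27.9 and 58.9, Rgs5 at 438 and 34.9, Msln at 137 and 413, and Epcam at 877 and 513. S phase genes had a median log2 difference from fresh cells of 1.08 at 24 h and 3.05 in the library titled 48h, above 99.9% and 100% of 10000 random lists matched for expression. G2 and M phase genes were at −0.17 and 4.09, and the latter median exceeded all random lists, with 33 of 33 genes above fresh cells. Hepatocyte markers were at −3.56 and −2.13, immediate early genes at −2.27 and −2.63, and NF-kB genes at −2.13 and −1.76, each below all random lists. Ductal identity (−0.63 and −0.83), transport and cilium (−1.24 and −0.53) and mesothelial markers (−2.96 and −1.75) lay below the central 95% of random lists in both libraries. So did cholesterol synthesis (−0.69), MYC and ribosome biogenesis (−0.38) and immune markers (−2.54) at 24 h, and interferon response (−0.78) in the library titled 48h, where glycolysis (1.03) lay above it. Random lists take no account of correlation between genes, and with an estimated correlation camera gave adjusted p of 0.764 and 0.332 for S phase, 0.955 and 0.243 for G2 and M phase, 0.508 and 0.172 for hepatocyte markers, the same values for immediate early genes, and 0.76 and 0.531 for NF-kB genes. For the other lists outside the central 95% it gave between 0.172 and 0.916. With each lone library assumed to vary like the other groups, limma counted 1409 genes at 24 h (550 higher, 859 lower) and 427 in the library titled 48h (237 higher, 190 lower). The median log2 change of genes with a mean of at least 5 RPKM was 0.30 and 0.45. After centring on the library medians the counts became 534 and 1588, and 193 and 408. The majority at 24 h turned with a pseudocount of 5, to 618 higher and 537 lower. In the library titled 48h it also turned with a pseudocount of 0.1 (49 and 65), after quantile normalization (332 and 390) and with voom (112 and 163). Without either fresh library both counts were 0 (2417 and 2322 at an unadjusted p under 0.05 at 24 h, 1790 and 1534 in the library titled 48h), and the 24 h count was 2313 or 2303 without 12 h replicate 1 or 2.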

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

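The tests of bias, composition and hypoxia genes were chosen only after the glycolysis difference between the organoid libraries was seen. Those of bias and hypoxia genes were written before their own results were seen, that of composition after.

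Changes from fresh cells differed between 12 h and 6 days for 258 genes, tested in limma as organoids against 12 h cultures. With only these groups in the model 0 passed (1686 at an unadjusted p under 0.05), and 28 passed with libraries weighted by their estimated spread. These weights were 2.66 for each fresh library, 0.6 at 12 h and 0.502 in organoids. The shared estimate of spread thus drew on fresh libraries that varied less than the groups compared. The count was 0 without either fresh library, either 12 h library or organoid replicate 1 (1679, 1687, 2777, 2767 and 2074 at an unadjusted p under 0.05). Of the genes named by the rule, 29 differed, 16 higher and 13 lower in organoids. Among them, genes of the cell cycle were higher at 6 days by log2 differences of 5.80 for Cdkn3, 5.67 for Cdc20, 5.56 for Ube2c, 5.18 for Ccnb2, 4.94 for Aurka, 4.70 for Rrm2 and 2.68 for Mki67. Also higher were Slfn2 by 6.38, the noncoding RNA Wincr1 by 5.26, Igfbp4 by 5.18, Mmp7 by 5.03, Sp5 by 3.52, Cxcl5 by 3.46, Msln by 3.46 and Ereg, a ligand of the EGF receptor, by 1.79. The genes lower at 6 days included Rgs5 at −7.12, Apoe at −6.87, H2-Q6 at −5.46, Nrn1 at −5.43, Cd74 at −5.04, Fosl1 at −4.52, G0s2 at −4.36, Nqo1 at −4.12, F3 at −2.94, Gbp3 at −2.16, Hbegf at −2.15 and Klf6 at −2.07. Cdkn3 and Ereg were listed at 0 in both 12 h libraries and G0s2 in both organoid libraries, so their fitted values depend on the pseudocount. Slfn2 and H2-Q6 have close paralogs, which leaves their read assignment uncertain.

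In 9 lists the changes from fresh cells at 12 h and 6 days differed by camera at its preset correlation, 5 higher and 4 lower in organoids. Of the 9, 0 held with an estimated correlation, on 3 degrees of freedom (adjusted p from 0.331 to 0.517). The median log2 differences were 3.07 for G2 and M phase, 1.66 for glycolysis, 1.14 for S phase, 0.63 for cholesterol synthesis and 0.61 for p53 targets. They were −1.16 for interferon response, −1.14 for MYC and ribosome biogenesis, −1.08 for NRF2 targets and −0.70 for immediate early genes. The call of p53 targets ended without organoid replicate 2 (adjusted p = 0.106), and that of cholesterol synthesis without it (0.0552) or without 12 h replicate 2 (0.148). Leaving out 1 library moved several medians by over 1.5 times. Without organoid replicate 1 or 2 they were −0.38 and −2.03 for MYC and ribosome biogenesis, 0.38 and 2.79 for glycolysis, 1.73 and 0.58 for S phase and 1.18 and 0.30 for p53 targets. Without organoid replicate 2 they were 0.39 for cholesterol synthesis and −1.77 for interferon response. Without 12 h replicate 1 they were 0.76 for S phase, −1.81 for interferon response and 0.37 for p53 targets, and without 12 h replicate 2 0.41 for cholesterol synthesis.

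The glycolysis difference rested on organoid replicate 1, in which all 16 genes exceeded replicate 2 by a median log2 ratio of 2.34, and without it the camera call ended (adjusted p = 0.123). Removing the trend with GC content and length left a median of 2.37 over 15 genes, against −0.73 to 0.27 in the central 95% of matched random lists, which argues against that bias as the whole cause. Composition would move all but the most abundant genes by a common factor, and matched random lists for the 16 genes had medians of −0.64 to 0.47 in their central 95%, which argues against composition. Rescaling without the most abundant genes decides nothing, since its factor was 1.03. Hypoxia-response genes outside glycolysis were higher in replicate 1 in 18 of 19 cases with a median of 2.92, against −0.87 to 0.06 in matched lists, with Bnip3 at 441 and 0.852 RPKM, and Car9 as the exception at 3.33 and 24.7. Lower oxygen in that culture may account for both groups of genes as a hypothesis, and differences in density, medium or time of harvest stay open because the labels give nothing on them.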

How the results depend on the processing

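The runs without the 24 h library, with voom on reads recovered from RPKM and with library weights were chosen after the data were seen. A lone library shows no spread of its own, so its weight, 1.25 for both, was not estimated from one. The weighted counts for the 24 h library and the library titled 48h rest on that value. Counts are of genes past the threshold in limma, and the cause of each move was not tested except where fewer genes or libraries entered.

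For 12 h against fresh cells the count went from 878 to 423 with no filter, 545 without the variance trend, 461 with the library titled 48h as a second 24 h library, 1601 with library weights, and 0 to 1082 leaving out each library. For organoids against fresh cells it went from 1301 to 740 with no filter, 762 with the 48h library as 24 h, 434 with voom on 9339 genes, and 0 to 1418 leaving out each library. For organoids against 12 h it went from 258 to 418 with a pseudocount of 0.1, 141 with 5, 0 with no filter (3379 at an unadjusted p under 0.05), 151 at a mean of at least 5 RPKM, 0 with only these groups (1686), 8 with the 48h library as 24 h, 425 with voom, 28 with library weights, and 0 to 321 leaving out each library. For 24 h it went from 1409 to 2258 with a pseudocount of 0.1, 2122 median-centred, 678 with the 48h library added, 4526 with library weights, and 0 to 2313 leaving out each library. For the library titled 48h it went from 427 to 114 with a pseudocount of 0.1, 930 with no filter, 722 after quantile normalization, 275 with voom, 2690 with library weights, and 0 to 521 leaving out each library. A rule of no overlap and a 2-fold difference gave 4184, 4640, 3065, 6513 and 5182, where chance alone leaves 33.3% of genes without overlap between pairs of libraries and 66.7% against a lone library.

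The labels do not say whether replicate numbers pair the libraries, and they were not used as pairs because 1 of the correlations of same-numbered residuals (0.19, 0.22 and 0.02) was under 0.1. With them as a block the counts were 713, 1419 and 208. Without the 24 h library they were 900, 1314 and 259, and 430 for the library titled 48h.

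The 151 calls of named genes and 26 of lists kept their direction in each setting that tested them. For the genes this was largely fixed in advance and adds little support. Each passing gene had no overlap between groups, so leaving out a library could not reverse it, and several settings leave the fold unchanged. Of the 151, 129 still passed with a pseudocount of 0.1, 54 with no filter, 112 with only the groups compared, 90 with the 48h library as 24 h, 71 and 82 without 12 h replicate 1 or 2, 67 and 114 without organoid replicate 1 or 2, and 0 without either fresh library (150 and 149 at an unadjusted p under 0.05). Of the 26 lists, all passed with a pseudocount of 0.1, 22 to 25 leaving out each replicate library, and 0 with an estimated correlation. At 12 h the camera calls ended for ductal identity after quantile normalization (adjusted p = 0.148), for transport and cilium at a mean of at least 5 RPKM (0.224; 0.178 in organoids) and with only these groups (0.101), and for mesothelial markers with these groups (0.146) and the block (0.057). Reversals were met only in genes that had not passed, as the lack of overlap in passing genes had largely fixed in advance. Dnmt3b at 12 h was −0.36 with a pseudocount of 0.1, −0.29 median-centred, −0.55 with voom and −1.12 to 1.39 leaving out each library. After quantile normalization Lgr5, Epcam and Mki67 at 12 h were 0.29, 0.61 and 0.17. Leaving out each library gave −0.19 to 0.10 for Lgr5, −0.35 to 0.0949 for Epcam and −0.52 to 0.17 for Sox9 at 12 h, −0.0484 to 0.59 for Krt19 and −0.44 to 0.0171 for Tet2 in organoids against fresh cells, and, in organoids against 12 h, −0.34 to 0.10 for Epcam, −0.61 to 0.21 for Spp1 and −2.15 to 0.37 for Dnmt3b. Epcam there was 0.0712 median-centred. Depth limits genes far under 1 RPKM, since 1 read in a 2 kb gene is up to 0.0361 RPKM.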

Other observations

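The tests on hepatocyte markers and on the library titled 48h, and the choice of class II, immune and transient genes, were made only after those results were seen.

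Genes of class II antigen presentation were lower in organoids than in fresh cells. Cd74 was at 257 and 254 RPKM in the fresh libraries, 136 and 100.4 at 12 h, 15.9 at 24 h, 0.13 in the library titled 48h and 1.90 and 3.44 in the organoids. H2-Ab1 went from 37.4 and 24.8 RPKM to 0 in both organoid libraries, and H2-Aa and H2-Eb1 were also listed at 0 there. Of 6 class II genes tested, 4 passed by limma, all lower, and H2-DMa (adjusted p = 0.299) and H2-DMb1 (0.0642) did not, with a median log2 change of −3.71, and camera gave an unadjusted p of 3.9e-07, or 0.0138 with an estimated correlation. These genes were chosen because of their values, so the p-values are no independent evidence. Of the immune markers tested, Csf1r was at 5.21 and 10.9 RPKM in fresh cells, 0.0977 and 0.443 at 12 h and 1.92 and 1.79 in organoids (adjusted p = 0.0308 at 12 h and 0.0777 in organoids). The others, Cd68 and Lyz2, were at 21.7 and 7.57 and at 2.07 and 1.89 RPKM in fresh cells and at 22.1 and 7 and at 1.66 and 2.62 in organoids, and the list had a camera adjusted p of 0.368 there. Loss of antigen-presenting cells, which sorting for EpCAM would remove, was not excluded as a reason for the fall.

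A group of 28 genes was higher at 12 h than in fresh cells and then lower in organoids than at 12 h, where 2.47 would be met if the calls were independent. Another 19 genes went the opposite way, where 6.62 would be met, but both comparisons share the 12 h libraries, which by itself raises such counts. Many of the 28 were predicted genes or small RNAs, which the rule for named genes leaves out, or pseudogenes, at low levels. Gm45027, for example, was at 2.45 and 4.13 RPKM at 12 h and listed at 0 in all other libraries. The 28 are therefore not shown to be a shared program of ductal genes. Tesc, which regulates a sodium-proton exchanger, was at 26.8 and 28.6 RPKM in fresh cells and 108 and 97.1 at 12 h, and at 9.09 and 5.07 in organoids. Angpt2, an antagonist of the receptor Tie2, was at 0.0355 and 0.0666 RPKM in fresh cells and 8.97 and 3.33 at 12 h, and at 0 and 0.0804 in organoids. Among genes low at 12 h, Bcam, a laminin receptor, was at 70.9 and 80.9 RPKM in fresh cells and 16.3 and 18.4 at 12 h, and at 77.9 and 85.6 in organoids. Aldh1a2, which makes retinoic acid, was at 10 and 15.2 RPKM in fresh cells and listed at 0 in both 12 h libraries, and was at 15.6 and 23.7 in organoids. It was at 44.2 RPKM at 24 h and 16.5 in the library titled 48h. A lower capture of molecules at 12 h was not excluded for this gene.

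Hepatocyte markers were present in the fresh cells, with Alb at 488 and 660.1, Apoa1 at 103 and 39.4 and Ahsg at 71.4 and 43.2 RPKM, although sorting for EpCAM would remove hepatocytes. The tables argue against scaling of the RPKM values as the cause of the later fall, since the 12 h median was −3.30 after centring on the library medians. RNA carried over from hepatocytes could be a source, which predicts that 1 profile scales all markers alike in both fresh libraries. The log2 ratios of 19 markers between those libraries had an SD of 1.04, within the 0.29 to 1.48 of matched random lists. That SD was wider than in 94.4% of the lists, so the markers did not scale closely alike. It stayed inside the limits, so the test leaves that source open. Expression of these genes by the ductal cells themselves was not told apart from carried-over RNA here, because both allow a fall in culture and the test of 1 profile did not decide.

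The library titled 48h is given as 24 h in its other labels. Over genes with a mean of at least 50 RPKM its correlation with the 24 h library across genes, which are not independent replicates, was 0.722, against 0.73 for the lowest replicate pair. That difference is well within the spread of the replicate pairs (SD 0.0884), a margin set after the value was seen, so the correlation does not decide whether it is a second 24 h culture. Organoid replicate 2 (0.844) and 12 h replicate 1 (0.783) correlated with it better, which goes against a second 24 h culture, but organoid replicate 2 was also closer to it than to its own replicate (0.73). Its G2 and M phase genes exceeded those of the 24 h library by a median log2 difference of 4.13, against at most 0.95 within a replicate pair, which argues against a plain replicate. Neither value tells the true hour of harvest, and cultures of the same hour that divide at different rates stay possible.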
